A study of Mus musculus with 9 samples.

How the data were processed

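RNA was measured in 9 samples of mouse CD4+ T cells collected on day 9 of experimental autoimmune encephalomyelitis (EAE), 4 labelled wildtype and 5 labelled as estrogen receptor alpha (ERα) knockout. The labels place 2 wildtype and 3 knockout samples in batch 1 and 2 wildtype and 2 knockout samples in batch 2. Total RNA was extracted with a column kit, made into libraries with the Ovation kit and sequenced as single-end reads, per the labels' protocols. Salmon 1.2.0, R 4.0.3 and the GRCm39 build are named in the submitters' processing notes, without their roles. The annotation release, the strand setting, the step from transcripts to genes and any filter are not given in the sources used here.

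The authors deposited 1 table of estimated counts (expected counts) for 39253 genes, each with an Entrez identifier, a symbol and a product name, per the file headers. The values were not whole numbers and summed to a different total in each library, so they had not been scaled to a common depth. The nonzero values were all fractional, so a scaling by transcript length cannot be excluded, and rounded values are called counts on the assumption that they estimate numbers of reads. They were rounded to whole numbers for the count models. Reads shared between near-identical genes are divided by estimation in such values, so members of tandem families are uncertain, and genes that overlap on opposite strands cannot be told apart. Totals ran from 4926347 to 11296593 counts in batch 1 and from 45013017 to 69844721 in batch 2. A floor of 3 counts corresponded to 0.043 to 0.609 CPM (counts per 1e6 counts of the library), depending on the library. Intervals and floors cover counting error only, on the same assumption.

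The main comparison used edgeR 4.0.16 in R 4.3.3: the quasi-likelihood test with robust estimation, TMM scaling, the tool's default low-count filter (minimum count 10, minimum total 15), and a model with batch and genotype. It tested 22197 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same test was run within each batch, for the interaction of batch and genotype, and for the batch term. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values in the text are counts divided by the library total. With nothing in the labels on which samples come from separate animals, p-values measure the spread between these samples.

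There were 26 gene lists and 15 marker lists, of which 38 had at least 3 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The mitochondrially encoded list had 0 matched genes. Where list members were adjusted over their list alone, the number of lists was not corrected for. Genes named in the text follow a rule: 13 fixed genes, genes past the threshold with the same sign in both batches, up to 4 called members of each list and, where fewer than 12 genes pass, the 12 genes with the smallest p, leaving out predicted, clone-named, pseudogene and receptor-segment names. The tests, lists, naming rule and most alternatives were written before the data were examined. Other genes are said to be chosen after their values were seen. Of the genes chosen in advance to be named in any case, 1 is not reported here.

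Alternatives were the omission of the batch term, a replicate block, DESeq2 1.42.0 size factors and Wald test, upper-quartile scaling, other filters, limma-voom with and without sample weights, a surrogate variable (sva 3.50.0), a component of non-T-cell markers, and leaving out each sample. In simulated data with 67, 67 and 66 genes changed by the 3 fold sizes, the main model recovered 2.99% of genes changed 1.5-fold, 29.9% of those changed 2-fold and 47.0% of those changed 4-fold, with 6 false calls among 22197 genes. The batch 1 test recovered 42.4% and the batch 2 test 59.1% of genes changed 4-fold, with 3 and 17 false calls. No libraries of a group and batch agreed within sampling noise, with chi-square per degree of freedom from 4.80 to 153.

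Chromosome class and gene order came from a RefSeq table of assembly GRCm38, which matched 96.4% of the identifiers. The deposited table uses another build, so no coordinates are given.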

Results

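CD4+ T cells from mice with EAE, an induced autoimmune disease of the central nervous system used as a model of multiple sclerosis, were profiled by RNA sequencing on day 9. The series title concerns ERα signalling in dendritic cells, while the measured cells were CD4+ T cells. The labels do not say in which cells the knockout acts, the tissue of origin or the sex of the mice. There were 4 wildtype and 5 knockout libraries. In batch 1, wildtype replicates 1 and 2 had totals of 11296593 and 4926347 counts, and knockout replicates 1, 2 and 3 had 7517788, 8713129 and 5069169. In batch 2, wildtype replicates 3 and 4 had 69844721 and 45013017 counts, and knockout replicates 4 and 5 had 62863222 and 54625373.

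Esr1, which encodes ERα, was examined first because it is the targeted gene. In batch 2 it had 101 and 76 counts in the wildtype libraries and 9 and 14 in the knockout libraries. These correspond to 1.57 ± 0.17 CPM (SD, n = 2) and 0.20 ± 0.080 CPM (SD, n = 2). Summed over libraries, Esr1 was 7.87-fold lower in the knockout, with a 95% exact binomial counting interval of 5.08 to 12.7 if the estimated counts are read as numbers of reads. The log2 fold change was -2.96 ± 0.70 (SE), and it did not pass adjustment over all genes (edgeR adjusted p = 0.618). In batch 1, Esr1 stood at 10.6 ± 8.04 CPM (SD, n = 2) in wildtype and 9.64 ± 3.35 CPM (SD, n = 3) in knockout libraries. The batch 1 libraries also held counts in sensory receptor genes, at up to 0.253% of the total, so the level of Esr1 in them does not check the genotype labels. Over both batches the log2 fold change of Esr1 was -1.41 ± 0.64 (edgeR adjusted p = 1.00).

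**Figure D1:**
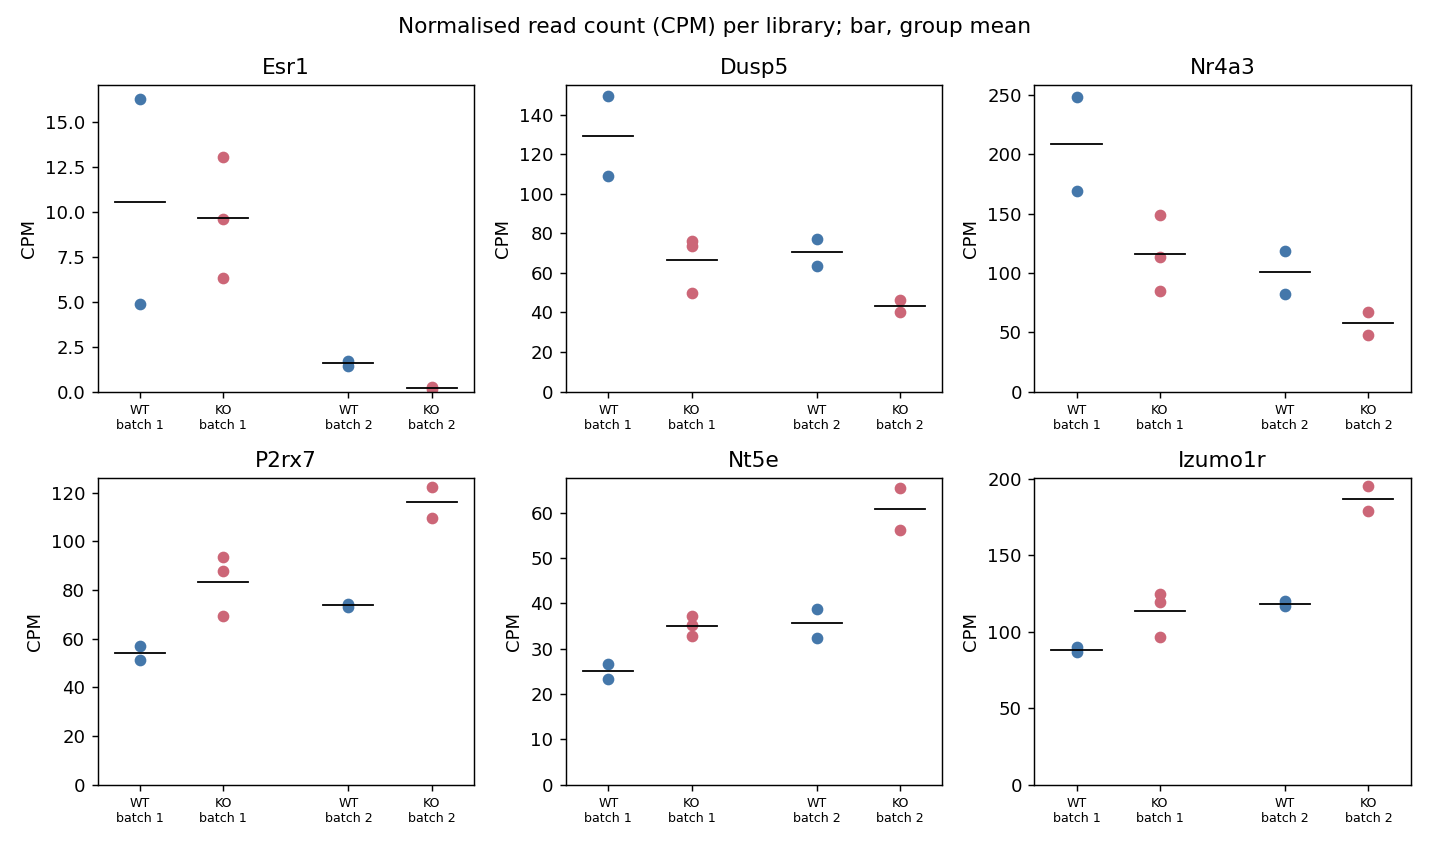
CPM of 6 genes (vertical axes, starting at 0) in wildtype (WT, blue) and ERα knockout (KO, red) libraries of each batch; points are libraries and bars are group means. Esr1 was lower in both batch 2 knockout libraries, and the other 5 genes had the same direction in both batches without passing the adjusted test. These 5 were among the genes with the smallest p over both batches, a choice that favours a shared direction.

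The comparison of knockout with wildtype asks which transcripts differ in CD4+ T cells between samples with these labels. A single gene, Adgrg4, an adhesion G protein-coupled receptor, passed the threshold among 22197 tested. It was lower in the knockout, with a log2 fold change of -4.17 ± 0.20 (edgeR adjusted p = 0.000543). Adgrg4 had 1055 and 496 counts in the batch 1 wildtype libraries, 38, 44 and 31 in the batch 1 knockout libraries, and 0 in all 4 batch 2 libraries, so the call rested on batch 1. Without wildtype replicate 1 there were 0 calls, without wildtype replicate 2 there were 2, and without wildtype replicate 4 there were 3. At an unadjusted p under 0.05 there were 523 genes, or 2.36% of those tested. DESeq2 called 16 genes, and gave no adjusted p for 8617 of the 22197 genes.

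The genes with the next smallest p did not pass the edgeR threshold and are given as values. Lower values in the knockout came first. Dusp5, a phosphatase that inactivates ERK, had a log2 fold change of -0.86 ± 0.17, and the nuclear receptor Nr4a3 had -0.85 ± 0.20, each with an edgeR adjusted p of 1.00. Nr4a3 and Nr4a1 were the 2 genes called in the list of early T cell receptor response genes when adjusted over the list alone, against 0 of its 16 tested members over all genes. Nr4a1 had -1.06 ± 0.28. Srgap3 had -1.04 ± 0.26 and Iqcn -0.98 ± 0.22.

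Other genes had higher values in the knockout. The ATP-gated channel P2rx7 had a log2 fold change of 0.62 ± 0.13, Nt5e (CD73, an enzyme that makes adenosine) 0.59 ± 0.13, and Izumo1r (folate receptor 4, found on regulatory and anergic T cells) 0.47 ± 0.12. Nt5e and Izumo1r were the 2 genes called in the list of inhibitory receptors and anergy when adjusted over the list alone, with 0 of 17 over all genes. Izumo1r was also the 1 gene called in the regulatory T cell list adjusted over that list alone. Rnf122 had 0.87 ± 0.19, Chic1 0.85 ± 0.19, Col11a2 0.59 ± 0.13 and Ntrk3 0.51 ± 0.11. P2rx7, Nt5e, Rnf122, Chic1, Col11a2, Ntrk3 and Dusp5 passed the threshold in DESeq2. That test adjusted over fewer genes than edgeR, and it also gave more genes an unadjusted p under 0.05, 835 against 523.

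T helper genes did not pass the test. Il17a had a log2 fold change of -1.77 ± 0.99, Csf2 -1.21 ± 0.84 and Ifng -0.91 ± 0.48, while Foxp3, the regulatory T cell factor, had 0.31 ± 0.21. Tbx21 had -0.12 ± 0.40, Gata3 -0.12 ± 0.14 and Il10 0.37 ± 1.01. Il17a was at 1.87 ± 0.70 CPM in wildtype and 0.19 ± 0.14 CPM in knockout libraries of batch 2 (SD, n = 2 each), and at 1.08 ± 1.23 CPM (SD, n = 2) and 1.02 ± 0.84 CPM (SD, n = 3) in batch 1. Cd4 and Cd3e had -0.11 ± 0.11 and -0.03 ± 0.12. Itgax, the dendritic cell integrin, had -0.78 ± 0.55, and Esr2 had 1.42 ± 1.09.

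Of 38 lists tested with camera at a preset correlation, 13 passed, 11 lower and 2 higher in the knockout. With an estimated correlation 0 passed (lowest adjusted p = 0.909), and fry called 0 (lowest adjusted p = 0.948). The lower lists were those of dissociation and heat shock, proliferation, type I interferon response, histones, ribosomal proteins, monocytes and macrophages, Th17 cells, oxidative phosphorylation, the unfolded protein response, neutrophils, and memory and effector surface molecules. Of 28 proliferation genes 28 had a negative fold change, with a median of -0.40, and 0 passed the test singly. Of 21 Th17 genes 16 were negative, with a median of -0.43, and of 30 type I interferon genes 25 were negative, with a median of -0.27. The regulatory T cell list had a median of 0.31, with 17 of 21 genes positive, and the cholesterol synthesis list 0.12, with 17 of 19 positive. When each of the 9 libraries was left out in turn, the regulatory T cell list passed in 5 of the 9 runs and the cholesterol synthesis list in 1. Their medians fell to 0.094 and 0.039 at the lowest, and the camera direction of both turned without wildtype replicate 2 and with a replicate block. The lower lists passed in 4 (neutrophils) to 9 (dissociation and heat shock) of these runs, with 5 for the unfolded protein response, and the direction of the neutrophil list turned without wildtype replicate 3 and with the block. The dissociation and heat shock list did not pass when wildtype replicate 3 and knockout replicate 3 were both left out.

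The batches did not give the same picture. Among the 13 lists, 9 had the same camera direction in both batches, 2 passed in both batches, and 0 passed in both in the same direction. With an estimated correlation 0 lists passed in batch 1 (lowest adjusted p = 0.977) and 0 in batch 2 (lowest adjusted p = 0.802). The proliferation list had a median log2 fold change of -0.03 in batch 1 and -0.97 in batch 2. The dissociation and heat shock list had -0.02 in batch 1, with 10 genes higher and 10 lower, and -0.66 in batch 2. The ribosomal list had -0.38 in batch 1 and 0.15 in batch 2. The neutrophil list had 0.36 and -3.84. In batch 2, wildtype replicate 3 had 150488 Mki67 counts (2155 CPM) against 1036 CPM in wildtype replicate 4, and its neutrophil marker S100a8 stood at 56.1 CPM against 7.47 CPM. Without wildtype replicate 3, 8 lists passed, 7 of them among the 13, and without knockout replicate 4, 7 passed, all among the 13. Without wildtype replicate 1, 5 passed, of which 2 were among the 13, and the Th17, proliferation and type I interferon lists no longer passed.

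**Figure D2:**
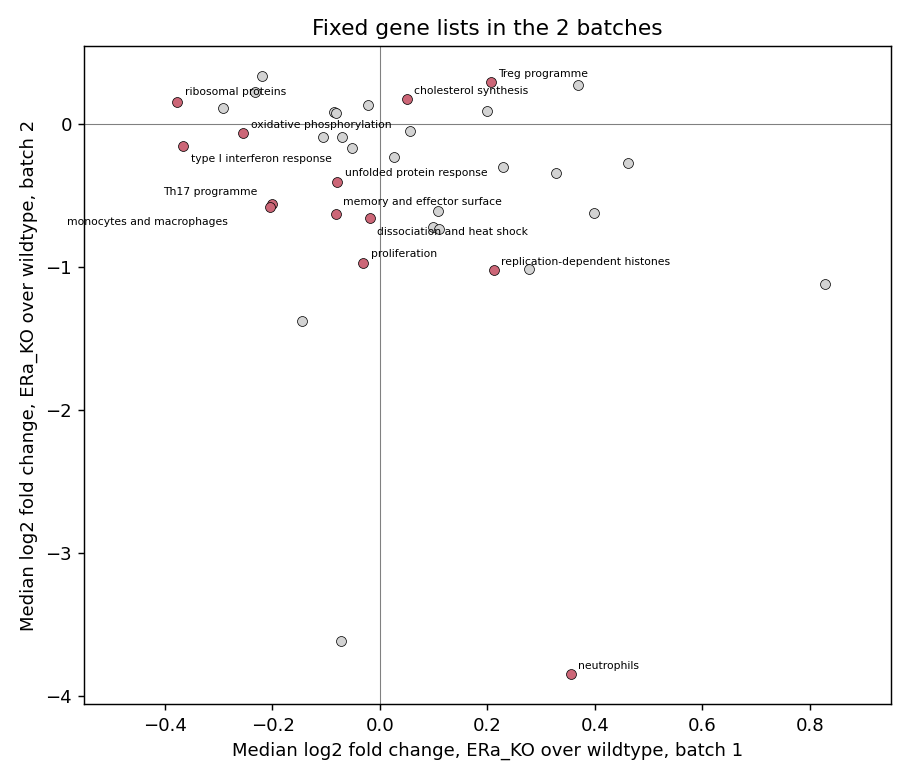
Median log2 fold change of each fixed list, knockout over wildtype, in batch 1 (horizontal axis) and batch 2 (vertical axis); red points passed camera over both batches and grey points did not. The ribosomal list lies at -0.38 and 0.15, and the neutrophil list at 0.36 and -3.84.

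Within batch 1, 31 genes passed, 18 higher and 13 lower in the knockout, of 24600 tested. Zfp965, a zinc finger gene, had a log2 fold change of -3.68 ± 0.38 (edgeR adjusted p = 1.01e-09). Wls, which carries Wnt proteins to the cell surface, had 2.66 ± 0.41, and the interferon-induced gene Oasl2 had -2.55 ± 0.41. Map7 had -2.15 ± 0.37 and H60b, a ligand of an NK cell receptor, 5.51 ± 0.95. These 5 genes were chosen after their values were seen. Of the 31 genes, 18 could be tested in batch 2, where 10 had the same direction and 2 had an unadjusted p under 0.05. The count was 56 with DESeq2 size factors, 31 of them higher, and 6 with upper-quartile scaling, 1 of them higher. The median log2 fold change of all batch 1 genes was 0.04 with TMM, -0.08 with DESeq2 size factors and 0.11 with upper-quartile scaling. The count was 61 without wildtype replicate 1 and 118 without wildtype replicate 2, where the lone wildtype library is assumed to vary like the knockout.

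Within batch 2, edgeR called 0 of 15910 genes, with 1237 (7.77%) at an unadjusted p under 0.05, and DESeq2 called 329. Without wildtype replicate 3 edgeR called 268 and without wildtype replicate 4 it called 879. When adjusted over the list alone, 48 of 63 histone genes and 19 of 28 proliferation genes passed, as did 10 of 20 dissociation and heat shock genes, which include Jun at -1.06 ± 0.16. Members of a list vary together, with an estimated correlation of 0.44 for histones and 0.71 for proliferation, so they are not independent results. Of 19 naive and quiescence genes 6 passed in this way, among them Dapl1 at 0.81 ± 0.15. Il22 and Il23r passed in the Th17 list, at -2.74 ± 0.33 and -1.58 ± 0.31. The members named for batch 2 were chosen after their values were seen, and wildtype replicate 3 had the highest proliferation and neutrophil marker levels of that batch.

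The interaction test asked whether the genotype difference depended on the batch, and 1 gene passed. Zfp965 had an interaction log2 fold change of 4.07 ± 0.29 (edgeR adjusted p = 0.000653). It stood at 52.7 and 68.0 CPM in batch 1 wildtype libraries and at 5.45, 4.82 and 4.93 CPM in batch 1 knockout libraries. In batch 2 it was at 34.8 and 33.8 CPM in wildtype and 54.9 and 40.4 CPM in knockout libraries. Without wildtype replicate 4 the test called 238 genes, without wildtype replicate 3 it called 13, and without knockout replicate 3 it called 6. It called 2 without wildtype replicate 2 and 2 without knockout replicate 5. Across 15288 genes tested in both batches, the fold changes of the batches had a Pearson r of -0.0908, where genes are not independent replicates.

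The batches differed in far more genes than the genotypes. The batch term passed for 14221 genes, 3724 higher and 10497 lower in batch 2, and with upper-quartile scaling for 12494, of which 1353 were higher. The median log2 fold change of all genes was -0.76, and -0.97 with upper-quartile scaling. The 1505 olfactory, vomeronasal and taste receptor genes, which are normally silent in T cells, took 0.0563% to 0.253% of counts in batch 1 libraries and 0.00196% to 0.0032% in batch 2 libraries. Genes with at least 1 count numbered 32046 to 34085 in batch 1 and 17008 to 18309 in batch 2. Sex-linked genes also followed the batches. Xist, expressed from the inactive X chromosome, was at 2640, 1740, 2680 and 2370 CPM in wildtype replicates 1 and 2 and knockout replicates 1 and 2. It was at 30.4 CPM in knockout replicate 3, and at 0 to 0.289 CPM in batch 2. The Y-linked gene Ddx3y had 55.4 CPM in knockout replicate 3, 93.6 to 107 CPM in batch 2 and 0 counts in the 4 other batch 1 libraries.

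**Figure D3:**
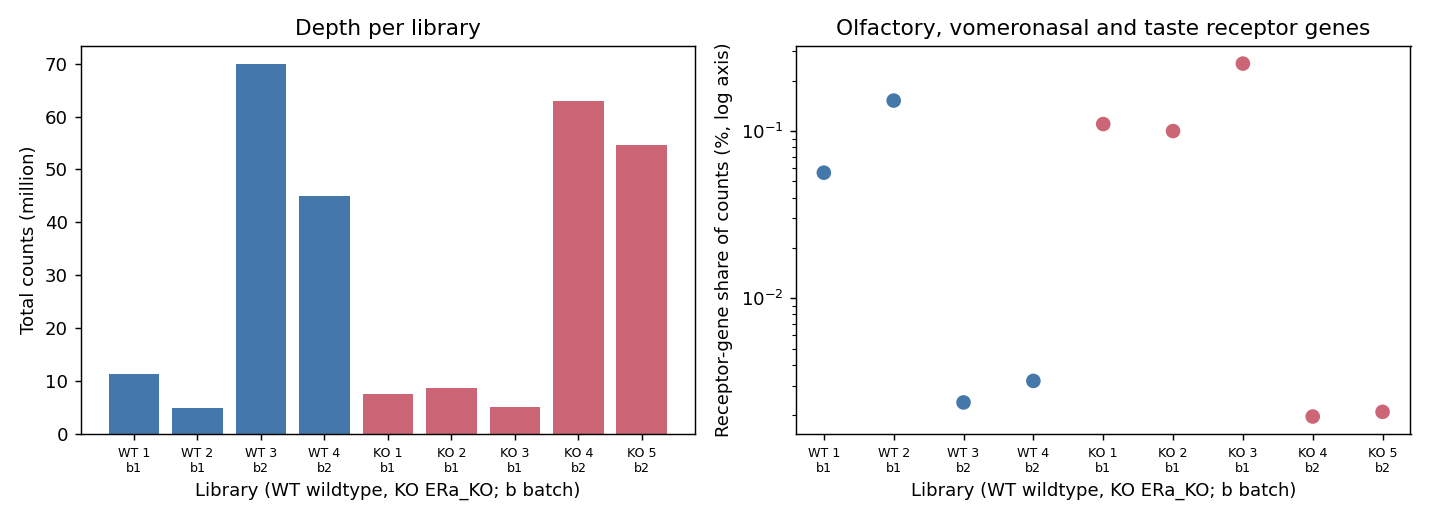
Total counts in units of 1e6 (left, bars from 0) and share of counts in receptor genes in percent (right, log axis) for each library, wildtype in blue and knockout in red. Batch 1 libraries lie at 0.0563% or above and batch 2 libraries at 0.0032% or below.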

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

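All tests of explanations in this part were chosen after the results were seen, except those of the spread of silent-gene counts, of gene order and of the Esr1 background, whose bounds were written first. Of 134 groups of libraries examined for a sample far from the others, 2 stood out. Chance would give about 6.70 in groups of alike libraries, but each group pooled both batches, which can hide a lone sample. The 2 are therefore not compared with chance. Csf2 was at 2.13 CPM in knockout replicate 1 and between 0.115 and 0.592 CPM in the other knockout libraries. The dissociation and heat shock list had a mean log2 CPM of 8.55 in wildtype replicate 3 and 7.68 to 7.80 in the other wildtype libraries.

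The genotype difference of 12 lists differed between batches with camera at a preset correlation, and of 0 with an estimated correlation (lowest adjusted p = 0.577). Their median interaction log2 fold changes, batch 2 minus batch 1, were -4.48 for neutrophils, -1.54 for NK cells, -1.41 for histones, -1.17 for proliferation, -0.96 for Th1 cells, -0.92 for dissociation and heat shock, and -0.81 for memory and effector surface molecules. They were 0.57 for naive and quiescence genes, 0.43 for ribosomal proteins, 0.28 for Tfh cells, 0.22 for CD4 T cell markers and 0.09 for oxidative phosphorylation. Zfp965 was the single gene whose genotype difference differed between batches, by 4.07 on the log2 scale.

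The first pattern is the presence of counts in batch 1 for genes with none in batch 2. Greater depth is argued against, since the lowest batch 1 receptor count was 3.83 times the highest batch 2 count although batch 1 was shallower. RNA of other cell types is argued against by the spread of the counts: the top 1% of 15061 silent genes held at most 11.5% of their counts in any batch 1 library. Genomic DNA in the libraries may account for it, from the mean count per X-linked silent gene over that per autosomal silent gene. This ratio was 0.534 in knockout replicate 3, the batch 1 library with Y-linked transcripts, and 1.04 to 1.30 in the 4 others. The relative value was 0.477, with a 95% bootstrap interval of 0.401 to 0.541. Apart from RNA of other cell types, no biological explanation was tested for this pattern.

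The second pattern is the set of 31 genes called within batch 1. Whether an uneven DNA background that follows the receptor genes lies behind the 31 genes could not be decided. Its share was 0.0563% in wildtype replicate 1 and 0.253% in knockout replicate 3, yet each gene called lower was higher in wildtype replicate 1. It was 0.152% in wildtype replicate 2 and 0.0999% in knockout replicate 2, yet each gene called higher was lower in wildtype replicate 2. These libraries were part of the calls, so the order of the called genes in them was largely set by the call. It does not test this background, and a background particular to single genes could not be excluded either. In a call from wildtype replicate 2 and knockout replicates 1 and 2 alone, 1022 genes were lower in the knockout, and 1015 of them differed between the libraries left out. Of these, 177 had wildtype replicate 1 above knockout replicate 3, and 838 had it below, as the receptor background of these libraries predicts (17.4% above, 95% exact binomial interval 15.2% to 19.9%, where genes are not independent). In a call from wildtype replicate 1 and knockout replicates 1 and 3, 25 such genes were higher, and 17 had wildtype replicate 2 below knockout replicate 2, against the background (46.5% to 85.1%). In both, a lone wildtype library is assumed to vary like the knockout. Most genes in these calls were not among the 31 (1009 of 1022 and 15 of 26), a condition set after the result was seen, so they do not decide for the 31. Sex is argued against as the cause of the batch 1 calls, since both wildtype libraries and knockout replicates 1 and 2 were female-type. Without knockout replicate 3, the male-type library of batch 1, 35 genes passed, 19 of them among the 31, and each of the 31 kept at least 0.763 of its log2 fold change. Strain variants that differ between the genotypes in batch 1 may contribute: 12 called genes had another within 50 places in gene order, where 95% of random draws had 6 or fewer, and 7 of 30 lay on chromosome 10 with Esr1, where random draws had a median of 1 (p = 4e-04, one-sided permutation, a count chosen after the genes were seen). Without Gm and LOC names, many of them in tandem families that share reads, only 2 of 15 had such a neighbour, which random draws reached often (p = 0.246, one-sided permutation). A genotype effect of similar size in both batches is argued against for the 18 genes tested in batch 2, where the median ratio of the batch 2 to the batch 1 log2 fold change was 0.0199 (95% exact interval -0.0892 to 0.126). The interval treats genes as independent, and the genes were chosen by their batch 1 values, which lowers the ratio. Their median absolute log2 fold change was 2.69 in batch 1 and 0.462 in batch 2. A genotype effect particular to batch 1 stays open, with 10 of the 18 in the same direction in batch 2, and it cannot be told apart from strain variants that go with the knockout. Whether sex underlies the difference from batch 2, where all libraries were male-type, was not tested.

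The third pattern is the lower Esr1 in knockout libraries of batch 2. Cells with neutrophil markers in wildtype replicate 3 are argued against as the source. Esr1 there was 0.856 times its CPM in wildtype replicate 4, which lacked the high neutrophil markers. Wildtype replicate 4 had the higher monocyte and macrophage list, at a mean log2 CPM of 4.32 against 3.77 in wildtype replicate 3. That list was at 3.27 and 3.63 in the batch 2 knockout libraries, so fewer such cells could not be excluded. Fewer dendritic cells could not be excluded: 6 dendritic cell markers at low levels had a median log2 fold change of -0.247, and Itgax had -1.75. The Itgax value rests on wildtype replicate 4, at 8.55 CPM, against 2.06 CPM in wildtype replicate 3 and 1.70 and 1.37 CPM in the knockout libraries, while Esr1 was at 1.69 and 1.45 CPM in wildtype replicates 4 and 3. Deletion of Esr1 stays open as the labelled cause. Its check in batch 1 was void, because only 63.1% of the silent genes had an exon length, and the knockout excess of 0.779 times the wildtype excess is therefore not read.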

How the results depend on the processing

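Alternatives added after seeing the data were the 5 CPM minimum over batch 2, the receptor-gene covariate, and the run without wildtype replicate 3 and knockout replicate 3. All alternatives within the batches except DESeq2 size factors were also added then. So were upper-quartile scaling in the batch test and leaving out samples in the interaction and batch tests. Unless stated, the cause of a change was not tested. The 1 gene of the genotype comparison became 0 without the batch term, 0 with the non-T marker component, 0 with limma-voom quality weights and 0 with the 5 CPM minimum, which removes Adgrg4. It became 2 with no low-count filter, 2 with a surrogate variable, 2 with the receptor-gene covariate and 16 with DESeq2, and ranged from 0 to 3 when single samples were left out. limma-voom also called 1 gene, a different one, Gm52481. The 13 lists became 0 with an estimated correlation and 0 with fry, and 5 (without wildtype replicate 1) to 18 (without wildtype replicate 2) with single samples left out.

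Replicate numbers do not pair the samples across the series, since replicate 3 lies in different batches. Deviations from the genotype mean log2 CPM correlated at 0.781, 0.838, -0.838 and 0.85 between same-numbered samples. Such deviations carry the batch difference, so they do not test pairing within a batch. With the replicate block 0 genes and 22 lists passed, and camera direction turned for the Treg list (median 0.024), cytotoxic effectors (0.0028), cholesterol synthesis (-0.012) and neutrophils (0.34). By the deviations from the genotype mean, not every wildtype sample correlated best with the knockout sample of its own number.

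Camera direction also turned for the Treg list (median 0.11) and cholesterol synthesis (0.039) without wildtype replicate 2, for neutrophils without wildtype replicate 3 (-0.091), and for neutrophils (0.075) and erythroid cells (0.39) without wildtype replicate 3 and knockout replicate 3. With 1 sample left out, the medians ranged from 0.094 to 0.36 for the Treg list, from 0.039 to 0.13 for cholesterol synthesis and from -2.66 to -0.091 for neutrophils. In these, a median and its camera direction can differ in sign. Of 516 values of named genes under alternatives, 504 kept their side of the threshold, with 6 changes of sign among uncalled values. All named genes except Adgrg4 were far from the threshold, so this count does not measure the stability of their fold changes. Of 713 list values, 613 kept their side of the threshold, with 100 changes of direction in all.

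The 31 genes of batch 1 became 56 with DESeq2 size factors and 6 with upper-quartile scaling, and 33 to 118 when single samples were left out. The 0 of batch 2 became 329 with DESeq2 and 0 to 879 with single samples left out. In both batches, a lone library is assumed to vary like the other group. The 1 interaction gene became 2 with no low-count filter and 1 to 238 with single samples left out. The batch count ranged from 11456 to 18656. In the shallowest library, with 4926347 counts, 3 counts make 0.609 CPM, against 0.043 CPM in the deepest; whether depth limits the calls in batch 1 was not tested.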

Other observations

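The erythroid list had a mean log2 CPM of 7.86 in wildtype replicate 3 and 2.87 in wildtype replicate 4, and its haemoglobin gene Hbb-bs was at 110 and 6.64 CPM. In batch 1, S100a8 was at 140 to 354 CPM in all 5 libraries, against 1.99 and 2.54 CPM in the batch 2 knockout libraries. The list of estrogen receptors and target genes did not pass camera (median log2 fold change 0.08, adjusted p = 0.76), with 10 of 18 genes positive.

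A hypothesis, chosen after the values were seen, is that the knockout samples may hold a larger share of regulatory T cells. In batch 2 the log2 fold changes of Nt5e and Izumo1r were 0.77 ± 0.16 and 0.66 ± 0.10 (SE). In batch 1 they were 0.33 ± 0.36 and 0.21 ± 0.37, no larger than their standard errors. Both genes were named for a small p over both batches, which favours a shared direction. The other 20 members of the regulatory T cell list had a median log2 fold change of 0.271, against a mean of 0.533 for the pair. With an estimated correlation their p was 0.356, so the hypothesis stays open.

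Other splits of the samples do not exclude chance for the genotype comparison. Of 100 splits into 4 and 5, 16 gave at least the 1 gene of the real split, and the highest other gave 32 genes. That split set wildtype replicate 3 alone against the other batch 2 libraries and wildtype replicate 2 alone against the other batch 1 libraries, and so many calls point to a structure of the samples other than genotype, whose nature was not tested. Of the 16, 9 (the real one included) kept the batch 1 wildtype and knockout libraries apart and so repeat the contrast behind Adgrg4. Without the others of these 9, 8 of 92 splits gave at least 1 gene, which does not exclude chance either. Of these 8, only the real split had 2 batch 1 libraries in the group of 4. Among the 53 splits with that balance, 6 gave at least 1 gene, and the highest other gave 1. All 6 kept the batch 1 wildtype and knockout libraries apart and so repeat the same contrast, which leaves the question open. For the lists, 61 of 100 splits gave at least 13, and the highest other gave 25. For the batch comparison, 1 of 100 splits, the real one, reached 14221 genes and the highest other gave 4. The other splits had no batch term, so the batch difference added to their spread and lowered their counts. The gap between the real split and the others is therefore not a measure of chance.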
